A study of Mus musculus with 16 samples.

How the data were processed

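The series holds 16 records of 8 murine B cell lymphomas, 4 from Eµ-Myc mice and 4 from Eµ-Myc mice with Wrn Δhel on both copies. Each tumour appears under 2 processings, which the titles name Illumina GUI and Bioconductor lumi, so each tumour was counted once and n is 4 per genotype. Genotype came from the titles, and replicate numbers from the descriptions. Per the labels' protocols, RNA was extracted with Trizol, cleaned on RNeasy columns with DNase treatment, and copied to biotin-labelled cRNA with Ambion's MessageAmp kit.

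The deposited table of non-normalized values holds, per the file headers, the average bead intensity of each probe on a linear scale and a detection p-value for each probe and array. By Illumina's convention the detection p-value deposited by the authors sets each probe against the negative controls of its array. Both processed tables were found from their values to be quantile normalized between the arrays. The lumi table holds intensity as deposited on a linear scale after background subtraction, with 26.3% to 26.4% of values below 0. The Illumina GUI table holds a score as deposited, neither a linear intensity nor a log: above a lumi value of 1000, its square root equals log2 of the lumi value within 0.0102. The software versions and settings behind these tables are not given in the sources used here. The design had taken the GUI values to be linear or log2, so the test was run on their square root, which is on the log2 scale for bright probes but not shown to be so for dim ones. Lumi values under 1 were set to 1 before log2.

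The non-normalized table names its probes by another kind of identifier than the processed tables. Both hold 25697 probes, and they were joined by the ranks of each probe on the 8 arrays. All 25697 joined one to one, and identically through either processing. The best match was always much closer than the second (highest ratio of distances 0.185), and 99.99% of joins were unchanged when made from 4 arrays only. Gene symbols came from the platform annotation, updated through gene numbers or accessions to the gene table of assembly GRCm38.p6. Of the probes, 23978 had 1 symbol, 0 had several and 1719 were not listed with a gene. Of those with a symbol 23962 were matched by gene number, 9 by accession and 7 kept the annotation's symbol. The symbols of 8 were updated. That gene table was used for names and gene order only, since the build behind the probe design is not given in the sources used here.

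Signals were background corrected and normalized with neqc of limma 3.58.1 in R 4.3.3, with negative controls inferred from the detection p-values, an offset of 16, quantile normalization and log2. Fold changes are therefore on a scale with that offset, which understates the changes of dim probes. Probes detected at p under 0.01 on at least 4 of the 8 arrays were tested, 11024 in all, of which 642 had no gene name. They covered 7665 genes. Genotypes were compared with lmFit and eBayes (Wrn minus Eµ-Myc, two-sided), and a probe was called at a Benjamini-Hochberg adjusted p under 0.05. A probe not detected on any array of a group has only a bound there. For such probes the brighter group's mean was set against the mean, over the dim group's arrays, of the higher of the probe's own value and the lowest value among detected probes, and given as at least that fold.

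Before the data were examined, 38 gene lists were fixed, 23 of pathways and 15 of cell type markers, and 32 had at least 5 tested genes. They were tested with camera at a preset correlation of 0.01, with the brightest tested probe of each gene, two-sided, and adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Some genes stand in more than 1 list. Also fixed then were the grouping, the tests and the rule for named genes. That rule names Wrn, Myc and the tested Arf and p53 genes, up to 12 called genes in each direction with unfilled places taken, by unadjusted p, by genes whose groups do not overlap, the 4 members with the lowest p of each list past camera, 1 or 2 members of other lists, and the 5 lowest p in each direction between letters. Markers of sex were listed to state their balance. Named members of lists past camera between the letters, the second probes of named genes and the keratin genes were chosen after their values were seen.

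Letters were compared with genotype in the model, and their interaction with genotype was fitted as well. Because of how letters and replicate numbers fall, that interaction is the same contrast as replicates 1 and 3 against 2 and 4. Exact permutation tests ran over all 70 orders of the 8 tumours, two-sided. Genes near Wrn were compared with all other tested genes by Fisher's exact test. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the join, and matplotlib 3.10.9 for the figures.

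The fit was tested on simulated data made from the means and spread of these arrays, in 20 data sets with 200 of 11024 probes changed for the comparison of genotypes. It called 1.7% of probes changed by 0.5 on the log2 scale, 44.6% at 1, 90.8% at 2 and 97.5% at 3, with 5.34% of calls false, and called 0 probes when none was changed. A list of 20 genes shifted by 0.3 among 7665 genes was found in 95% of data sets. Genes were independent in these simulations, so they say nothing about lists of correlated genes.

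Alternatives covered the background correction, the normalization, the deposited values, the filter on dim probes, array weights, the variance model, the letter and the replicate number in the model, the list test, and leaving out each tumour. Leaving out the genes near Wrn, leaving out the tumours in which Eif2s3y was not detected, and the alternatives for lists between letters were chosen after seeing the data. The chip and position of each array are not given in the sources used here, so no batch could be tested. Probes without a gene name were tested but are not named.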

Results

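Gene expression was measured on Illumina bead arrays in total RNA from murine B cell lymphomas of 2 genotypes, with 4 tumours in each. Eµ-Myc mice carry the Myc oncogene under an immunoglobulin heavy chain enhancer and develop B cell lymphomas. The Wrn Δhel allele lacks part of the helicase domain of the Werner syndrome protein, and the second genotype, called the Wrn tumours here, carried it on both copies. Tumours are named by genotype and by the replicate number, 1 to 4, that the labels give. The labels also carry a letter, E or L, whose meaning they do not give: Eµ-Myc tumours 1 and 3 and Wrn tumours 2 and 4 carried E, and the other tumours L. Median probe signal lay between 49.9 and 52.8 per array, and between 10607 and 11369 of 25697 probes per array (41.3% to 44.2%) were detected above the negative controls. Correlations between tumours over tested probes ranged from 0.945 to 0.984, so no array was a copy of another. The labels do not say that the tumours came from separate animals, so p-values measure only the spread between these samples, part of which may be technical, and the number of arrays limits the precision.

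The first comparison asked how the targeted gene, the driving oncogene and the Arf and p53 genes stood in each tumour. Wrn signal was 7.03, 7.48, 7.33 and 7.46 on the log2 scale in Wrn tumours 1 to 4, and 8.06, 8.45, 8.21 and 7.56 in Eµ-Myc tumours 1 to 4. The means were 7.33 ± 0.20 and 8.07 ± 0.38 (SD, n = 4), a difference of -0.75 ± 0.22 (SE). Every Wrn tumour lay below every Eµ-Myc tumour (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 tumours allow), but the difference did not pass the test over all probes (limma adjusted p = 0.973). A second Wrn probe was not detected on any array. Whether the measured probe lies inside the deleted part is not given in the sources used here, so the lower signal checks the genotype labels only as far as that allows.

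Myc signal differed by 0.36 ± 0.42 (SE, n = 4 per genotype, limma adjusted p = 0.973). It was 6.92 in Eµ-Myc tumour 2 and between 8.5 and 9.13 in the other 7 tumours, and the difference turned to -0.14 without Eµ-Myc tumour 2. Cdkn2a, which encodes the tumour suppressors p16Ink4a and p19Arf, differed by 0.90 ± 0.71. Its signal was 6.91 in Eµ-Myc tumour 3 and between 9.11 and 11.08 in the others, and a second Cdkn2a probe was also lowest in that tumour, at 6.23. Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases, was highest in the same tumour, at 8.85, and its genotype difference of -0.40 ± 0.47 became 0.071 without it. Mdm2, the ubiquitin ligase of p53, differed by 0.28 ± 0.26, Bmi1, a Polycomb repressor of Cdkn2a, by -0.46 ± 0.32, Cdkn2c by 0.22 ± 0.25, Cdkn1b by 0.20 ± 0.21 and Usp7 by 0.10 ± 0.17. None of these genes passed the test (limma adjusted p of 0.973 for each, except 0.986 for Usp7). Cdkn2b, Mdm4, Twist1 and Tbx2 were too dim to be tested, and Trp53 was not analysed here.

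**Figure D1:**
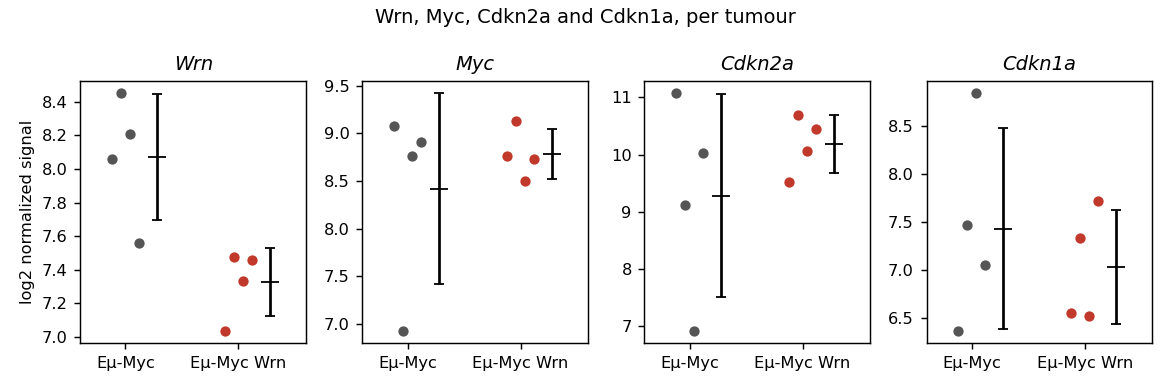
Normalized log2 signal of Wrn, Myc, Cdkn2a and Cdkn1a in each of the 4 Eµ-Myc (grey) and 4 Wrn (red) tumours, with the mean and SD as bars. The Wrn values do not overlap, whereas Myc is lowest at 6.92 in Eµ-Myc tumour 2, and Eµ-Myc tumour 3 has the lowest Cdkn2a, 6.91, and the highest Cdkn1a, 8.85.

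The main comparison asked which genes differed between the 2 genotypes. A probe of Mak16, which acts in ribosome assembly, fell by 5.18 ± 0.22 on the log2 scale (SE), from 9.81 ± 0.11 in Eµ-Myc tumours to 4.63 ± 0.42 in Wrn tumours (SD, n = 4, limma adjusted p = 1.48e-06), and was detected in 1 of the 4 Wrn tumours. A probe of Saraf, a regulator of store-operated calcium entry, rose by 1.94 ± 0.21, from 6.31 ± 0.17 to 8.25 ± 0.36 (limma adjusted p = 0.01004). A probe of Mtus1, which encodes a microtubule-associated protein, rose by 2.12 ± 0.27, from 4.56 ± 0.10 to 6.69 ± 0.60 (limma adjusted p = 0.0263). It was not detected in any Eµ-Myc tumour, which makes the difference at least 3.64-fold. Its log2 fold change ran from 1.15 with a normexp offset of 50, where the call was lost (limma adjusted p = 0.216), to 3.63 in the deposited lumi values. On the square root of the GUI values, not shown to be a log2 scale for dim probes, it differed by 3.66. Erdr1, erythroid differentiation regulator 1, rose by 4.68 ± 0.60, from 5.68 ± 1.51 to 10.35 ± 0.32 (limma adjusted p = 0.0263), and was detected in 2 of the 4 Eµ-Myc tumours. For each of these 4 probes the values of the genotypes did not overlap.

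**Figure D2:**
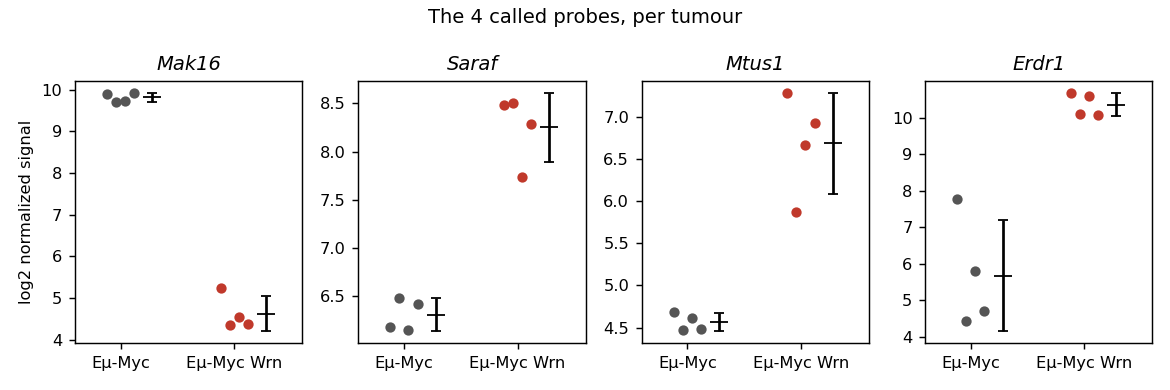
Normalized log2 signal of the 4 probes that passed the test, per tumour, with mean and SD as bars and n = 4 per genotype. Mak16 lies between 9.70 and 9.92 in Eµ-Myc tumours and between 4.35 and 5.24 in Wrn tumours, and Erdr1 reaches 7.76 in Eµ-Myc tumour 1 but at least 10.06 in every Wrn tumour.

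Probes of the same gene did not always move alike. The second Mak16 probe differed by -0.18 (adjusted p = 0.986). Of the other Saraf probes, the first differed by -1.24 ± 0.20 (adjusted p = 0.0974) and the second by -0.73 (adjusted p = 0.973), opposite to the Saraf probe that rose. The second tested Mtus1 probe was detected in every Wrn tumour and in no Eµ-Myc tumour, a difference of at least 1.90-fold (adjusted p = 0.113), and the 4 further Mtus1 probes were not detected on any array. Mak16, Saraf and Mtus1 also lie close to Wrn: in the gene order of GRCm38.p6 they are within 50 protein-coding genes of it, as are Fut10, Eri1 and Ppp2cb below. Among the tested genes in that stretch, 12 of 30 reached an unadjusted p under 0.05, 6 higher and 6 lower, against 283 of 7635 tested genes elsewhere (40.0% against 3.71%, Fisher's exact p = 3.93e-10). Without Wrn itself the count was 11 of 29 (Fisher's exact p = 4.11e-09). The stretch was chosen after the calls were seen, and stretches of 10, 25 and 100 genes on each side held 4 of 8, 8 of 19 and 13 of 59 such genes.

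**Figure D3:**
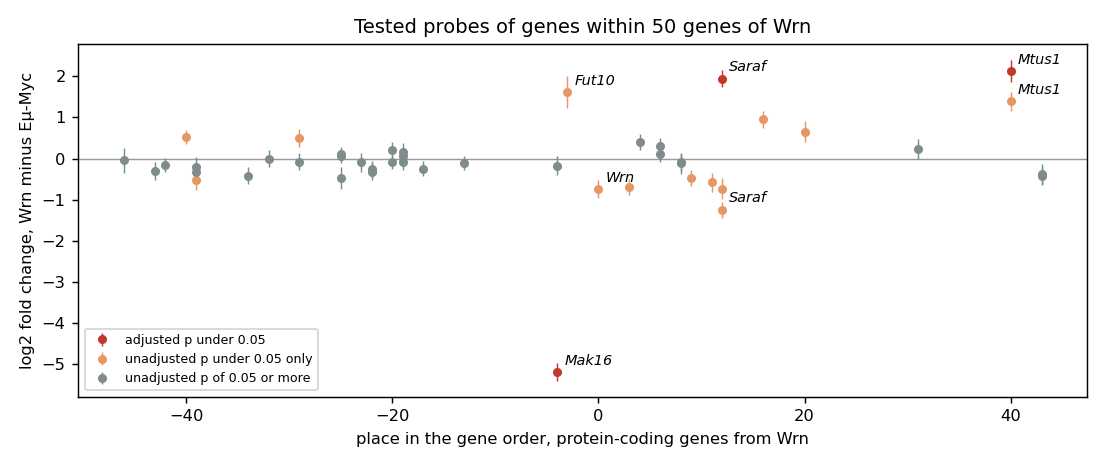
Log2 fold change (Wrn minus Eµ-Myc, with its SE) of each tested probe of genes within 50 protein-coding genes of Wrn, by place in the gene order. Probes past the test (Mak16 at -5.18, Saraf at 1.94 and Mtus1 at 2.12) lie on both sides of 0, and another Saraf probe lies at -1.24.

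In all, 4 of 11024 tested probes passed, 3 higher and 1 lower in Wrn tumours. At an unadjusted p under 0.05 there were 415 probes, 227 higher and 188 lower, where chance alone gives 551 on average. The groups did not overlap for 244 probes, or 2.21%, against a chance share of 2.86%. The named genes that follow did not pass (limma adjusted p between 0.875 and 0.973). Higher values in Wrn tumours were measured for Fut10, a fucosyltransferase, at 1.61 ± 0.38, with Eµ-Myc tumour 1 at 6.37 and the other Eµ-Myc tumours between 4.46 and 4.58. The 3'-5' exoribonuclease Eri1 differed by 0.95 ± 0.20, the zinc finger genes Zfp473 and Zfp11 by 0.93 ± 0.21 and 0.88 ± 0.20, Enox2 by 0.92 ± 0.23 and the transcriptional repressor Hbp1 by 0.79 ± 0.18. Gmip, Spcs3, a subunit of the signal peptidase, and Plekha1 differed by 0.76 ± 0.21, 0.75 ± 0.18 and 0.59 ± 0.15. Lower values were measured for the protease inhibitor Slpi at -1.66 ± 0.39, Nubp2 at -1.19 ± 0.29, the RNA-binding gene Stau2 at -1.15 ± 0.30 and the histone gene H3c3 at -1.08 ± 0.24. H3c3 was not detected in any Wrn tumour, a difference of at least 1.68-fold. Aifm2, a suppressor of ferroptosis, differed by -0.89 ± 0.21, Ccdc124 by -0.74 ± 0.19, Rilpl1 by -0.72 ± 0.20, the phosphatase subunit Ppp2cb by -0.69 ± 0.20 and Derl2, of endoplasmic reticulum degradation, by -0.64 ± 0.17.

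The Mak16 call held in each of 20 alternative fits that gave it a value, with limma adjusted p from 4.77e-07 to 0.00899, whereas Saraf passed in 16 of 21, Erdr1 in 7 of 21 and Mtus1 in 6 of 20, each in its direction throughout. Sizes differed between processings: the log2 fold change of Mak16 was -3.78 and that of Erdr1 3.69 with a normexp offset of 50, against -7.28 and 5.74 in the deposited lumi values. Saraf did not pass without Wrn tumour 1, Wrn tumour 4 or Eµ-Myc tumour 3 (limma adjusted p = 0.0738, 0.0621 and 0.0591). When 1 tumour was left out, Erdr1 passed only without Eµ-Myc tumour 1 and Mtus1 only without Wrn tumour 2, with limma adjusted p from 0.067 to 0.182 and from 0.0599 to 0.156 in the other cases. The number of probes past the test was 1 without Wrn tumour 1, Wrn tumour 4 or Eµ-Myc tumour 3, and 2 without Wrn tumour 3, Eµ-Myc tumour 2 or Eµ-Myc tumour 4.

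Gene lists fixed for pathways and cell types were compared next. Markers of macrophages and monocytes were lower in Wrn tumours in 18 of 18 tested genes, with a median of -0.49 (camera adjusted p = 6.68e-09, adjusted p = 0.553 with an estimated correlation). Among them the complement gene C1qc differed by -0.58 ± 0.20, the Fc receptor genes Fcer1g and Fcgr3 by -0.78 ± 0.26 and -0.60 ± 0.24, and the adaptor gene Tyrobp by -0.53 ± 0.22. The genes of MHC class II presentation were higher in 10 of 10, with a median of 0.50 (camera adjusted p = 1.11e-04, adjusted p = 0.553 with an estimated correlation). Ciita, the master regulator of this class, differed by 0.64 ± 0.27, H2-Ob by 1.03 ± 0.34, H2-DMb2 by 0.92 ± 0.40 and the invariant chain Cd74 by 0.57 ± 0.30. Pan-B cell markers were higher in 12 of 12, with a median of 0.20 (camera adjusted p = 0.00722, adjusted p = 0.674 with an estimated correlation). The kinase genes Btk and Blk differed by 0.56 ± 0.21 and 1.39 ± 0.57, Cd37 by 0.36 ± 0.24 and the B cell receptor chain Cd79a by 0.34 ± 0.23. The pan-B list did not pass without Eµ-Myc tumour 1 or 4 or Wrn tumour 4 (adjusted p = 0.0583, 0.0639 and 0.13), or with array weights (adjusted p = 0.0859), and the other 2 lists passed whichever tumour was left out. Beside these groups, markers of endothelium had a median of -0.0029, which turned to 0.011 under cyclic loess scaling, and those of fibroblasts and stroma one of 0.11. Markers of T cells and granulocytes had medians of -0.37 and -0.33 and did not pass camera.

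**Figure D4:**
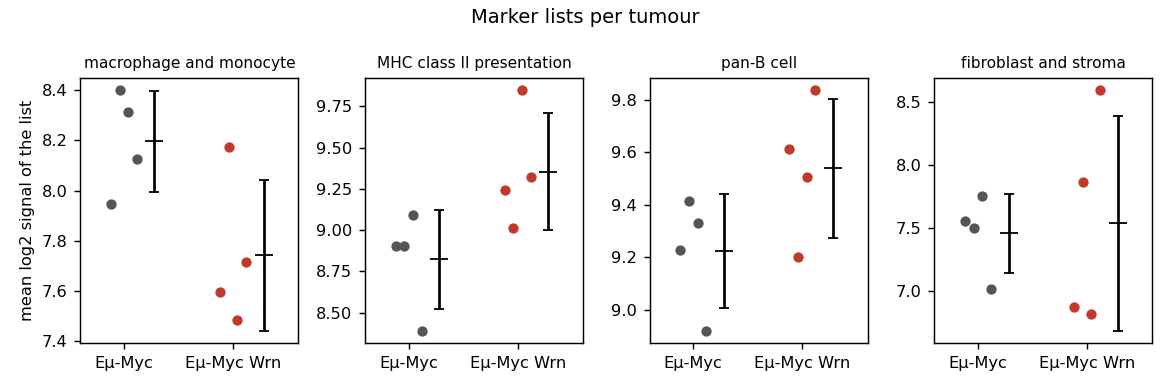
Mean log2 signal of the macrophage and monocyte, MHC class II, pan-B cell, and fibroblast and stroma lists in each tumour, with mean and SD as bars and n = 4 per genotype. The macrophage mean is 7.74 ± 0.30 in Wrn tumours against 8.20 ± 0.20 in Eµ-Myc tumours with 1 Wrn tumour, at 8.17, among the Eµ-Myc values, and the stromal means are 7.53 ± 0.86 and 7.46 ± 0.31.

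Genes of the interferon response were lower in Wrn tumours in 22 of 26, with a median of -0.26 (camera adjusted p = 8.78e-04, adjusted p = 0.674 with an estimated correlation). Bst2, Isg15, Ifit3 and Igtp, all induced by interferon, differed by -0.56 ± 0.25, -0.80 ± 0.39, -1.11 ± 0.55 and -1.06 ± 0.52. Igtp was 9.58 in Eµ-Myc tumour 2 and between 7.15 and 7.34 in the other Eµ-Myc tumours, and without that tumour the median of the list was -0.039 and the list did not pass (adjusted p = 0.700). Genes of NF-kB and the early response were lower in 15 of 19, with a median of -0.11 (camera adjusted p = 0.0271, adjusted p = 0.674 with an estimated correlation). The early transcription factor Egr1 differed by -1.26 ± 0.55, the chemokines Ccl3 and Ccl4 by -0.84 ± 0.39 and -0.80 ± 0.46, and the inhibitor Nfkbib by -0.56 ± 0.30. Adipocyte markers were lower in 5 of 5, with a median of -0.48 (camera adjusted p = 0.0197, adjusted p = 0.674 with an estimated correlation), among them Pparg at -0.40 ± 0.21, Lpl at -0.48 ± 0.31, Lipe at -0.25 ± 0.17 and Car3 at -0.72 ± 0.68. With 1 tumour left out, the NF-kB list passed only without Eµ-Myc tumour 3 or 4 or Wrn tumour 4 (highest adjusted p otherwise 0.369, without Eµ-Myc tumour 2). It also did not pass under median scaling (adjusted p = 0.0561) or with detection on all 8 arrays (adjusted p = 0.0581). The adipocyte list did not pass without Eµ-Myc tumour 1, 2 or 3 or Wrn tumour 4 (adjusted p = 0.0583, 0.125, 0.136 and 0.118), or with no filter (median -0.25, adjusted p = 0.110).

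Genes of the Myc network, Myc among them, were higher in Wrn tumours in 6 of 6, with a median of 0.39 (camera adjusted p = 0.00377, adjusted p = 0.370 with an estimated correlation). Mxd4 and Mga, which oppose Myc, differed by 0.72 ± 0.20 and 0.42 ± 0.16, and Max, the partner of both, by 0.44 ± 0.23. The call rests on the filter: the list did not pass with no filter, with a median of 0.10 (camera adjusted p = 0.110), or with detection on 1 array, with a median of 0.15 (camera adjusted p = 0.0707). Genes of homologous recombination and the Fanconi pathway were higher in 12 of 17, with a median of 0.19 (camera adjusted p = 0.0271, adjusted p = 0.674 with an estimated correlation). Rad54b, Rad52 and Rad51d differed by 0.42 ± 0.21, 0.34 ± 0.17 and 0.40 ± 0.21, and the helicase gene Brip1 by 0.90 ± 0.50. Brip1 was 4.95 in Eµ-Myc tumour 4 and between 6.86 and 7.92 in the others. This list did not pass without Eµ-Myc tumour 1 or 4 or Wrn tumour 1 or 3 (adjusted p = 0.0995, 0.487, 0.0912 and 0.0889), and its median was 0.064 without Eµ-Myc tumour 4 and 0.082 without Wrn tumour 1.

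**Figure D5:**
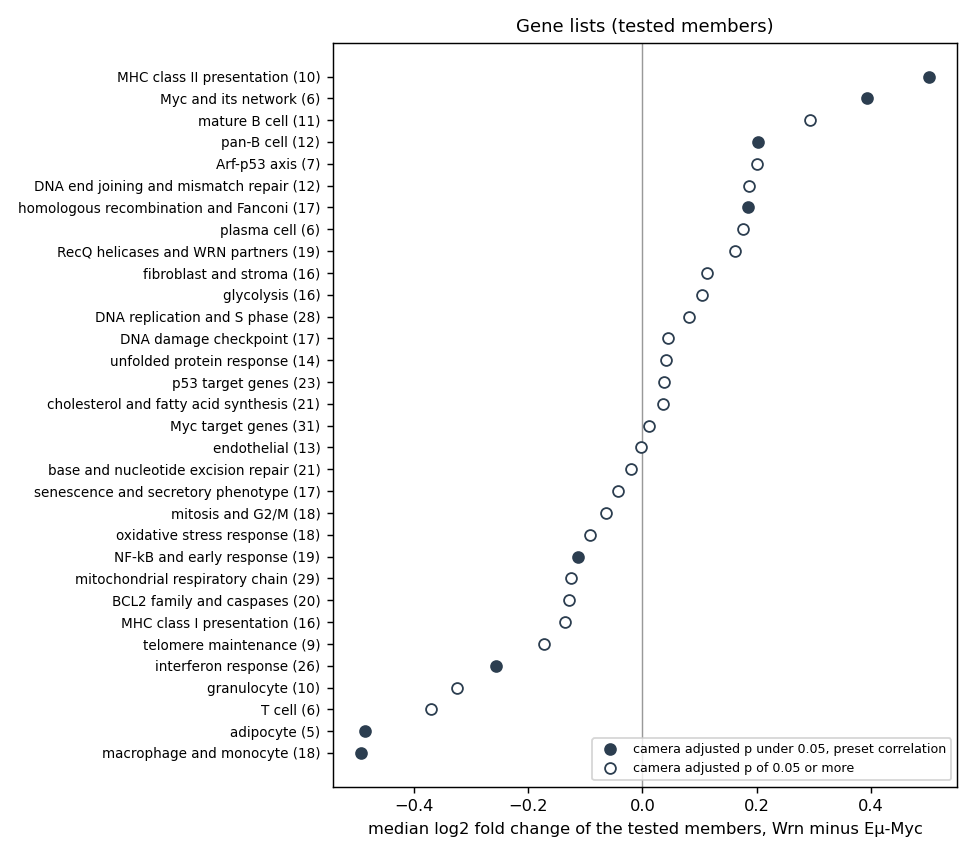
Median log2 fold change (Wrn minus Eµ-Myc) of the tested members of each of 32 lists, with the number of tested genes in brackets. Filled points passed camera with the preset correlation, from macrophage and monocyte markers at -0.49 to MHC class II presentation at 0.50, and none passed with an estimated correlation.

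Together 8 of 32 tested lists passed camera with a preset correlation of 0.01, and 0 passed with an estimated correlation or with fry (2 by each at an unadjusted p under 0.05). The smallest adjusted p of fry was 0.118. At an unadjusted p under 0.05, the list of macrophage markers held 5 genes, that of MHC class II 3, that of the Myc network 2, that of pan-B cells 2 and that of NF-kB 1, and the others that passed held 0. Of the members of the lists, 0 passed over all genes tested by limma, and adjusted over the list alone 1 did, Mxd4 (adjusted p = 0.0271). Without Eµ-Myc tumour 1, 4 lists passed. Over all alternatives the medians kept their sign but ran from -0.67 to -0.36 for macrophages, 0.28 to 0.64 for MHC class II, 0.13 to 0.32 for pan-B cells, -0.37 to -0.039 for the interferon response, -0.25 to -0.058 for NF-kB, -0.67 to -0.25 for adipocytes, 0.10 to 0.53 for the Myc network and 0.064 to 0.29 for homologous recombination.

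The remaining lists did not pass camera. Besides stroma, those with medians above 0.1 were mature B cell markers at 0.29, the Arf and p53 axis at 0.20, DNA end joining and mismatch repair at 0.19, plasma cell markers at 0.18, RecQ helicases and Wrn partners at 0.16, and glycolysis at 0.10. Among their members Xrcc6, the Ku70 subunit, differed by 0.53 ± 0.22, Prkdc, the DNA-dependent protein kinase, by 0.54 ± 0.23 and the B cell antigen Ms4a1 by 0.69 ± 0.41. Medians below -0.1 were those of T cell markers at -0.37, granulocyte markers at -0.33, telomere maintenance at -0.17, MHC class I presentation at -0.14, the BCL2 family and caspases at -0.13 and the mitochondrial respiratory chain at -0.13. Cd3d and Cd3g of the T cell receptor complex differed by -0.51 ± 0.57 and -0.47 ± 0.49, and turned to 0.19 and 0.13 without Eµ-Myc tumour 2. Closer to 0 were DNA replication and S phase at 0.081, the DNA damage checkpoint at 0.045, p53 targets at 0.038, the oxidative stress response at -0.092 and mitosis at -0.063. The median of Myc targets was 0.012, and turned to -0.0065 under cyclic loess and -0.031 under median scaling. Trp53inp1, a p53 target, differed by 1.14 ± 0.35 and the repair scaffold Xrcc1 by 0.64 ± 0.18, neither past the test (limma adjusted p = 0.973).

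The median and mean differed in sign for base and nucleotide excision repair (-0.021 and 0.032), senescence and the secretory phenotype (-0.042 and 0.019), cholesterol and fatty acid synthesis (0.036 and -0.027) and the unfolded protein response (0.041 and -0.039, with a median of -0.042 under median scaling). Camera gave the direction of the mean for excision repair and the unfolded protein response, and that of the median for senescence and cholesterol synthesis. For Myc targets camera pointed down while the median and mean of 0.023 were above 0. Lists with fewer than 5 tested genes were not tested. Their medians were 0.33 for pro- and pre-B cell markers, -0.27 for germinal centre B cells, -0.56 for NK cells, -0.69 for erythroid cells, -0.56 for the 1 dendritic cell gene, Bst2, and -0.59 for the 1 platelet gene, Pf4. The haemoglobin gene Hba-a1 differed by -1.21 ± 0.69 (limma adjusted p = 0.973).

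The letter in the tumour names was compared with genotype in the model, with 4 L and 4 E tumours. A probe of Dctn1, a subunit of the dynein activator dynactin, rose by 2.32 ± 0.23 (SE), from 4.82 ± 0.32 in E tumours to 7.15 ± 0.39 in L tumours (SD, n = 4, limma adjusted p = 0.0223). A probe of the splicing factor Prpf8 rose by 1.46 ± 0.17, from 6.36 ± 0.16 to 7.82 ± 0.20 (limma adjusted p = 0.0401). Neither call held in the deposited GUI values, in the deposited lumi values, with no filter or with the replicate number in the model, where 0 probes passed. No probe was lower in L tumours past the test, and 820 probes reached an unadjusted p under 0.05 where chance gives 551 on average. Chance counts vary widely when probes are correlated. Over the 35 ways to split the 8 tumours 4 against 4, 116 to 843 genes away from Wrn reached that threshold. These are counts of genes, not probes, and from fits without genotype. On that count the split by letter gave 604 genes, fewer than some other splits. The excess between letters therefore need not be more than chance. The next genes did not pass (limma adjusted p between 0.142 and 0.261). They included Ccnk at 1.49 ± 0.24, Zcchc18 at 1.36 ± 0.26 and Rbm10 at 1.11 ± 0.21 among the higher, and keratin gene Krt14 at -2.87 ± 0.48, the neutrophil granule gene Lcn2 at -1.87 ± 0.28, Plekha5 at -1.83 ± 0.27, the chemokine Ccl7 at -1.60 ± 0.25 and Igfbp4 at -1.38 ± 0.20 among the lower.

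Markers of fibroblasts and stroma were lower in L tumours in 15 of 16 genes, with a median of -0.81 (camera adjusted p = 8.97e-09), among them the collagen genes Col1a1 at -2.00 ± 0.35 and Col1a2 at -0.98 ± 0.23 and the chemokine Ccl21a at -3.19 ± 0.72. Granulocyte markers were lower in 10 of 10, with a median of -0.98 (camera adjusted p = 1.16e-07), among them S100a8 at -2.02 ± 0.57 and S100a9 at -1.82 ± 0.43. Endothelial markers were lower in 12 of 13, with a median of -0.47 (camera adjusted p = 3.18e-06), among them Vwf at -0.89 ± 0.19. Senescence and secretory genes were lower in 15 of 17, with a median of -0.35 (camera adjusted p = 2.92e-04), among them Timp1 at -1.45 ± 0.34 and Cxcl1 at -0.93 ± 0.27. Each of these 4 lists had an adjusted p = 0.504 with an estimated correlation. Interferon response genes were higher in 22 of 26, with a median of 0.22 (camera adjusted p = 0.0242, adjusted p = 0.993 with an estimated correlation). This rested on Eµ-Myc tumour 2, an L tumour with a list mean of 7.97 against 6.45 to 6.68 in the other L tumours: without it the median turned to -0.062 (camera adjusted p = 0.803). The list also did not pass without Eµ-Myc tumour 1 or Wrn tumour 3 (camera adjusted p = 0.516 and 0.0647), while the 4 lists lower in L tumours passed whichever tumour was left out. Their medians were weaker in places, at -0.53 for granulocytes and -0.25 for senescence without Eµ-Myc tumour 3, -0.29 for endothelium without Wrn tumour 3 and -0.54 for stroma without Wrn tumour 4. Macrophage and monocyte markers had a median of -0.088 (camera adjusted p = 0.615), which became -0.30 and passed without Eµ-Myc tumour 1 (camera adjusted p = 0.0326), and pan-B cell markers one of -0.059 (camera adjusted p = 0.974).

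Both tumours in which the Y-linked gene Eif2s3y was not detected, Eµ-Myc tumour 1 and Wrn tumour 2, carried the letter E. Their Xist signals, from the inactive X chromosome, were 7.46 and 7.33, against 4.18 to 5.17 in the others. Without these 2 tumours 0 probes passed limma between letters, with 1029 at an unadjusted p under 0.05, and 4 lists passed camera, with medians of -0.97 for stroma, -1.31 for granulocytes, -0.73 for endothelium and -0.53 for senescence, while the interferon list had a median of 0.10 (camera adjusted p = 0.573). With an estimated correlation 0 lists passed there, and 1 had an unadjusted p under 0.05. Leaving out Eµ-Myc tumour 1 or 4, or Wrn tumour 2, 3 or 4, also left 0 probes past limma between letters, with 819, 792, 874, 669 and 599 at an unadjusted p under 0.05, while 8 passed without Eµ-Myc tumour 2 and 5 without Eµ-Myc tumour 3.

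Whether the genotype difference depended on the letter was tested as an interaction. It reached 0 probes by limma (smallest adjusted p = 0.937), with 554 at an unadjusted p under 0.05, among 11024 tested. The spread between tumours was compared as well. The median SD over tested probes was 0.269 in Wrn tumours and 0.316 in Eµ-Myc tumours, a difference of -0.047 (exact two-sided permutation p = 0.343), and 59.1% of probes had the larger SD in Eµ-Myc tumours. The first 4 principal components held 24.8%, 21.3%, 17.4% and 12.6% of the variance, and the genotypes parted past the threshold on none of them (smallest exact permutation p = 0.0571, on the second).

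Each array had been deposited under 2 processings, which were set against each other. Across 11024 probes, which are not independent replicates, the genotype fold changes of both correlated with a Pearson r of 0.987, and a Spearman rho of 0.994. Within each tumour both processings ranked the probes alike (Spearman rho of 1.0). Agreement of their fold changes and calls was therefore largely set in advance and is no independent check. The same 3 probes, of Mak16, Saraf and Mtus1, passed limma in both and in the main comparison. Erdr1 differed by 5.76 on the square root of the GUI values, which is not shown to be a log2 scale for dim probes, and by 5.74 in the lumi values, and did not pass in either (limma adjusted p = 0.351 and 0.473).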

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

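No test in this part was chosen only after the result was seen. Each named gene and list mean was searched, within each genotype of 4 tumours, for 1 tumour far from the others: its gap to the nearest other tumour, divided by the whole range, had to be above Dixon's 95% critical value. Chance picks out about 1 in 20 groups. Of 194 groups 11 had such a tumour, where chance gives 9.7, so their number is no sign of more than chance.

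Eµ-Myc tumour 2 stood apart in 4 of them. Its Myc signal was 6.92 against 8.77 to 9.08 in the other Eµ-Myc tumours (ratio 0.854), and its mean over Myc target genes was 10.52 against 10.82 to 10.85 (ratio 0.903). Its interferon-induced gene Igtp was at 9.58 against 7.15 to 7.34 (ratio 0.922), and its mean over T cell markers was 7.83 against 5.93 to 6.25 (ratio 0.83). No explanation was tested for this tumour.

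In the other Eµ-Myc tumours, Fut10 in tumour 1 was 6.37 against 4.46 to 4.58 (ratio 0.935). The Saraf probe that was lower in Wrn tumours was 9.18 in Eµ-Myc tumour 3 against 9.44 to 9.47 (ratio 0.899). Nfkbib in Eµ-Myc tumour 4 was 7.25 against 5.98 to 6.04 (ratio 0.956). Among Wrn tumours, H2-Ob in tumour 3 was 9.08 against 8.2 to 8.3 (ratio 0.892), C1qc in tumour 2 was 10.46 against 9.9 to 9.93 (ratio 0.95), the T cell mean in tumour 2 was 6.96 against 6.04 to 6.08 (ratio 0.96), and the adipocyte mean in tumour 1 was 7.16 against 6.25 to 6.39 (ratio 0.849).

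For 63 named genes the genotype difference was also tested for a difference between the letters. By limma 0 passed, with a smallest adjusted p of 0.132 and 6 at an unadjusted p under 0.05.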

How the results depend on the processing

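Tests chosen only after the result was seen are those without the genes near Wrn, those without the tumours lacking Eif2s3y, and those of lists between letters. Of 2476 values of named genes under alternatives 2436 kept direction and side of the threshold, 33 lost and 1 gained the call, and 6 reversed. For 700 list medians these counts were 632, 23, 14 and 31, and of 113 counts and other main values 79 stayed within their bounds. All 33 losses among named genes fell on the 4 called probes: Erdr1 passed in 7 of 21 alternatives, Saraf in 16 of 21, Mtus1 in 6 of 20 and Mak16 in 20 of 20. The other named genes had not been called, so staying on their side of the threshold says little. No cause was tested, except where fewer genes, probes or tumours entered the fit. The chip as a block was not run, since no source gives it. Signal over background limits the dim probes: Mtus1 was detected in 0 Eµ-Myc tumours and Erdr1 in 2 of 4.

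Probes changed between genotypes numbered 1 with no filter, 2 with detection on 1 array, 1 with detection on all 8 arrays, 2 with array weights, 1 with the mean of a gene's probes, 1 with no variance moderation, and 0 without genes near Wrn, where limma left 399 at an unadjusted p under 0.05 and Erdr1 at an adjusted p of 0.106. They numbered 1 to 6 when 1 tumour was left out, against 4 in all tumours: 1 without Wrn tumour 1 or 4 or Eµ-Myc tumour 3, 2 without Wrn tumour 3 or Eµ-Myc tumour 2 or 4, and 6 without Eµ-Myc tumour 1. The replicate block left 2, Mak16 and Erdr1. Tumours that share a number did not deviate together (correlations -0.004, -0.175, -0.214 and -0.186), and 0 of the 4 Eµ-Myc tumours correlated best with the Wrn tumour of their own number, so the numbers were not taken to pair samples. The block left the 8 lists past camera and added 1.

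Lists past camera numbered 5 with detection on all 8 arrays, 0 with an estimated correlation and 0 by fry (2 by each at an unadjusted p under 0.05), and 4 to 9 when 1 tumour was left out (4 without Eµ-Myc tumour 1). Between letters, 0 probes passed limma in the deposited GUI values, the deposited lumi values, with no filter, with the replicate block added, and without the tumours lacking Eif2s3y (850, 824, 1645, 634 and 1029 at an unadjusted p under 0.05), and 0 to 8 when 1 tumour was left out (2 without Wrn tumour 1, 8 without Eµ-Myc tumour 2, 5 without Eµ-Myc tumour 3, and 0 in the other cases). With an estimated correlation 0 lists passed between letters (1 at an unadjusted p under 0.05). The interaction gave 1 probe in the GUI values and 1 in the lumi values (591 and 576 at an unadjusted p under 0.05). The correlation of the fold changes of both processings was 0.871 with no filter. The difference in spread kept its sign throughout.

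Medians near 0 reversed in places: Myc targets to -0.0065 (cyclic loess) and -0.031 (median scaling), endothelium to 0.011 (cyclic loess) and 0.0012 (no filter, and detection on 1 array), the unfolded protein response to -0.042 (median scaling) and cholesterol synthesis to -0.022 (array weights). With 1 tumour left out the ranges that crossed 0 were, for genes, -0.14 to 0.58 for Myc, -0.73 to 0.13 for Cd3g and -0.82 to 0.19 for Cd3d (each turned without Eµ-Myc tumour 2), -0.76 to 0.071 for Cdkn1a and -0.49 to 0.020 for Prtn3 (both without Eµ-Myc tumour 3), and -0.0033 to 0.75 for Acta2 (without Wrn tumour 4). For list medians they were -0.055 to 0.079 for Myc targets, -0.015 to 0.16 for p53 targets, -0.051 to 0.062 for the unfolded protein response, -0.19 to 0.17 for endothelium, -0.0074 to 0.16 for the checkpoint, -0.069 to 0.040 for excision repair, -0.12 to 0.013 for mitosis, -0.68 to 0.17 for T cells, -0.21 to 0.079 for senescence, -0.52 to 0.21 for granulocytes, -0.11 to 0.16 for cholesterol synthesis, -0.18 to 0.31 for stroma and -0.00093 to 0.33 for plasma cells.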

Other observations

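Tests chosen only after the result was seen are the share of changed genes near Wrn and its count over the splits, the disagreement of probes, the Mtus1 probes, the shares of non-B cells and the keratin genes; the other splits of the tumours and leaving out each tumour for the macrophage list were chosen before.

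Keratin genes, which epithelia such as skin express, varied widely between tumours, and 3 of the 7 looked for were bright enough to be tested. Krt14 was 7.81, 8.36 and 8.52 in 3 of the E tumours and 5.72 in the fourth, Eµ-Myc tumour 3, against 4.38 to 4.93 in the L tumours. Krt17 was 6.77, 7.51 and 7.16 in the same 3 tumours and 4.95 in Eµ-Myc tumour 3, against 4.28 to 4.49 in the L tumours. Krt10 was between 7.42 and 9.23 over all tumours, with Eµ-Myc tumour 4, an L tumour, the highest, so it did not follow the letter. The difference of Krt14 between letters did not pass the test (limma adjusted p = 0.187).

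Of the 4 probes called between genotypes 3 come from genes beside Wrn, and a candidate explanation is DNA of another mouse strain carried along with the targeted allele. Near Wrn 12 of 30 tested genes reached an unadjusted p under 0.05 (Fisher's exact p = 3.93e-10, odds ratio 17.3). The stretch was chosen after the calls were seen, so this count includes genes that picked it. Without the called genes 10 of 27 did (Fisher's exact p = 2.64e-08). The highest such count in a window of the same size on any other chromosome was 8. These last 2 values argue against a response spread evenly over the genome as the whole cause, although Fisher's test takes neighbouring genes as independent. For the number of changed probes, 1 of 35 splits of the tumours, the real one, gave as many (4, highest other 2). That is the smallest share 35 splits can give, so it makes chance less likely without excluding it. Without the genes near Wrn 0 probes passed. Erdr1, which is not among them, kept its log2 fold change of 4.68 there (limma adjusted p = 0.106, against 0.0263 with them). Its call was lost through the adjustment over probes, so this does not show that differences are confined to the neighbourhood of Wrn. The split count for genes beside Wrn, 1 of 35 splits (12, highest other 6), decides nothing, because the stretch was chosen from the calls of the real split. Probes of 1 gene disagreed more near Wrn than elsewhere (mean range 0.943 for 12 genes against 0.155 for 1950, one-sided permutation p = 1e-04, the smallest that 10000 permutations can give). Without Mak16, Saraf and Mtus1 the mean range near Wrn was 0.266 (one-sided permutation p = 0.0179). Sequence variants under some probes could give this. The range also grows with the size of the fold changes, whose median absolute log2 value was 0.359 near Wrn against 0.165 elsewhere. The test therefore cannot tell such variants from larger changes in expression. For Mtus1 variants stay open as well: both tested probes were higher in Wrn tumours by bounds of at least 4.08 SE, but where on the gene they lie is not given in the sources used here. An effect of the allele itself on its neighbours was not tested and stays open, and away from Wrn the genotype split gave 283 genes at an unadjusted p under 0.05, where 22 of 35 splits gave as many.

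Macrophage markers were lower and B cell and MHC class II genes higher in the Wrn tumours, a pattern that may come from the makeup of the tumours. Chance cannot be excluded for the number of lists: 19 of 35 splits gave as many (8 in the real split, highest other 12). The macrophage list alone had as small a camera p in 3 of 35 splits. It did not rest on 1 tumour, with a highest adjusted p of 9.32e-06 when 1 was left out, although with an estimated correlation its unadjusted p then ran from 0.00486 to 0.0988. Whether all non-B cells were fewer cannot be told apart from a change in macrophages alone. The macrophage score minus the endothelial and stromal scores differed by -0.49, or -1.51 SE, with an exact permutation p of 0.2 in 4 against 4 tumours. T cell and granulocyte markers, left out of that score, had medians of -0.37 and -0.33, neither past camera. A biological difference between the genotypes stays open.

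Stromal, endothelial and granulocyte markers were lower in the L tumours, and since the meaning of the letter is not given, only the makeup of the tumours was tested as an explanation. Chance cannot be excluded: 2 of 34 splits that could be fitted with genotype gave as many changed probes (2 in the real split, highest other 2) and 28 of 34 as many lists (5 in the real split, highest other 13). Not all of these splits are balanced over the genotypes as the letter is, so they are an imperfect reference. A smaller share of all non-B cells stays open, as the whole cause or as part of it. The stromal, endothelial and granulocyte score minus the macrophage and T cell score differed between letters by -0.88, or -2.61 SE. With 1 tumour left out it lay between -3.50 and -2.03 SE. This cannot decide, because the lists set against each other were picked after their shifts between letters were seen. The test set first, an exact permutation, gave p = 0.0571. Without Eµ-Myc tumour 2 the scores differed by -0.66, or -2.41 SE. There the T cell median turned from 0.46 to -0.35 and the macrophage median went from -0.088 to -0.19. Without Eµ-Myc tumour 1 macrophage markers were lower as well (median -0.30, camera adjusted p = 0.0326, with the scores then -2.28 SE apart). A smaller share of skin or other epithelium could lower such markers and stays open: the mean of Krt17 and Krt10 differed by -1.24 between L and E tumours (exact permutation p = 0.0571), which rests on Krt17 at -2.23, with Krt10 at -0.25. That test leaves out Krt14, whose value had been seen. Run first with Krt14, the mean differed by -1.79 (exact permutation p = 0.0286). The keratin genes were chosen after their values were seen, so neither p comes from unseen values.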
